A study of Homo sapiens with 11 samples.

How the data were processed

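The screen was run in MDS-L, an established human myelodysplastic/leukaemia cell line, grown per the labels' protocols with 10% fetal bovine serum and 10 ng/mL interleukin 3. The cells carried a lentiviral CRISPR library of guide RNAs against RNA-binding proteins (RBPs), in a vector that delivers the guide and Cas9 together. Guide inserts were amplified from genomic DNA by a pair of PCR steps and sequenced, so each value counts how often a guide was read, not how strongly a gene was expressed. PCR reads carried no molecular identifiers in the labels' protocols, and intervals of counting error therefore cover counting only. The labels gave 4 groups of 2 libraries, called biological duplicates: unsorted cells at day 0, unsorted cells at day 21, and GFP-high and GFP-low cells sorted at day 21. Nothing in the labels says that the duplicates came from separate cultures. P-values of single guides then measure the spread between these libraries only, which may be technical. In the main test, p-values of genes and lists compare their guides with other guides, taken as nearly independent. They do not measure how well a gene's result repeats between libraries. A further 3 samples of RNA from common myeloid progenitors are not analysed here.

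The count table holds, per the file headers, whole-number read counts per guide as the authors deposited them, with no normalisation. The authors' count summary gives the reads, the mapped reads and the mapped fraction of each library, and a Gini index, a fraction between 0 and 1 for unevenness over guides. How the counts were transformed before that index is not stated, and it differed from the Gini index of the raw counts. A further 5 columns per sample in that summary were not used. The authors' deposited gene table gives a beta score and a z score per gene for GFP-high and for GFP-low cells. It also gives permutation and Wald p-values with false discovery rates, per the file headers. It does not name the baseline of these scores. The submitters' processing notes name MAGeCK, cutadapt, Bowtie2 and the hg19 build, and which step each was used for, with which version, is not given in the sources used here. Gene coordinates were taken from the GRCh38 reference annotation by gene symbol. Guide sequences and cutting positions were not used here.

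The library held 12470 guides. Of these, 11402 targeted 1142 human genes, and 1129 genes had 10 guides, 12 had 9 and RPL41 had 4. Control guides numbered 1058, namely 267 against the AAVS1 locus, 711 under 71 names that begin with Zhang and 80 under 8 names that begin with CTRL. The names of the last 2 kinds show only that they target none of the RBP genes. The other 10 guides carried the names of fluorescent proteins: 3 EGFP, 3 tGFP, 2 mCherry, 1 BFP and 1 BPF. RUNX1 itself was not among the targeted genes. Total counts per library equalled the mapped reads in the summary for all 8 libraries.

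Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Libraries were scaled with edgeR's TMM factors, guides with a mean count under 10 were to be left out, and the filter removed 0 guides. All 8 libraries entered 1 quasi-likelihood fit with 4 group means and no block for the replicate number. Each guide's quasi-likelihood F statistic was turned into a signed z value. The guides of a gene were then tested against all other guides with limma's camera, with a preset correlation of 0.01. Genes with at least 3 guides were tested, 1144 in all, of which 1142 were human genes and the others EGFP and tGFP. P-values were adjusted by the Benjamini-Hochberg method over the genes, with a threshold of 0.05. A gene's log2 fold change is the mean over its guides, with the standard error (SE) over guides. Levels per library are mean log2 CPM, scaled with the TMM factors, over a gene's guides, with the SD over 2 libraries. The 4 comparisons were GFP-high with day 21 unsorted cells, GFP-low with day 21 unsorted cells, GFP-high with GFP-low, and day 21 with day 0 unsorted cells. TMM places the average guide near no change, and results relative to the control guides are given as well.

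Before the data were examined, 19 lists of RBP genes were fixed and tested with the same camera test over their guides, adjusted over the 19 lists. The named genes followed a rule fixed at the same time. It took the 10 genes with the smallest adjusted p in each direction past the threshold and, where fewer than 5 passed, the genes with the smallest p up to 5. HNRNPA1 and KHDRBS1 were added in every comparison, because the study named them from these samples. Up to 4 members of each list with the smallest p were also eligible. The rule also took 1 Y-linked gene, which is left out of the text. A few other results that the rule or a comparison took are not reported here. Alternatives tried were DESeq2 size factors, library totals and control-guide scaling, other count filters, a replicate block, fits of the 2 groups compared only, and leaving out each library in turn. Other gene-level tests were camera with an estimated correlation, rank-based camera, fry, control guides as the background, robust rank aggregation, at least 5 guides per gene, counts summed per gene and DESeq2 1.42.0. A voom fit with group variances and a fit of day 21 libraries only were chosen after seeing the data.

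The test was tried on simulated counts with the real guides' means, depths and group spreads, with 200 of 1144 genes changed. With every guide active, 2-fold changes were found for 41% of 100 genes in GFP-high against unsorted cells, 86% in GFP-low against unsorted cells, 43% in GFP-high against GFP-low and 100% at day 21 against day 0. For 4-fold changes these shares were 100%, 100%, 99% and 100%. With only some guides of each gene active, 2-fold changes were found for 4%, 12%, 1% and 61% of 100 genes, and 4-fold changes for 35%, 67%, 8% and 100%. None of 944 unchanged genes was called in any of them. The simulated changes were split evenly between higher and lower, all guides of a group shared a common spread, and libraries were drawn independently. In the real day 21 libraries, camera against control guides found 1049 genes lower and 0 higher than at day 0. The simulated shares and the lack of false calls may therefore not carry over to that comparison.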

Results

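The screen asked which RNA-binding proteins (RBPs) change the production of isoforms of RUNX1, a transcription factor of blood development. RUNX1 lies on chromosome 21 (34787801 to 36004667, GRCh38). Guide RNAs against 1142 genes were counted in genomic DNA of MDS-L cells, a human leukaemia line, carrying 1 CRISPR library. Unsorted cells were taken at day 0 and day 21, and GFP-high and GFP-low cells were sorted at day 21, with 2 libraries per group. Total counts were 10759126 and 9632439 at day 0, 8788906 and 8491118 at day 21, 4575140 and 4286130 in GFP-high cells, and 4002630 and 4295300 in GFP-low cells. The median guide had 850.5 and 761 counts at day 0, 587 and 569 at day 21, 271 and 266 in GFP-high, and 255 and 281 in GFP-low cells. Counting alone then gave a standard error of 3.43% to 6.26% at the median guide. At most 2 guides of 12470 had a count of 0 in any library.

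Agreement of the duplicates differed between the groups. Across guides, which are not independent replicates, Pearson's r of log2 CPM was 0.982 at day 0, 0.841 at day 21, 0.503 in GFP-high and 0.627 in GFP-low cells. The duplicates lay over 2-fold apart for 0% of guides at day 0, 12.5% at day 21, 51.3% in GFP-high and 36.7% in GFP-low cells. The biological coefficient of variation from edgeR was 2.68%, 31.7%, 73.2% and 57.2% in the same order, although the test pooled 1 spread over the 4 groups. The Gini index of the raw counts was 0.175 and 0.176 at day 0 and 0.4996 and 0.4672 in GFP-high cells. The index in the authors' deposited summary, on a scale not stated, was 0.0280 and 0.0287, and 0.130 and 0.121.

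**Figure D1:**
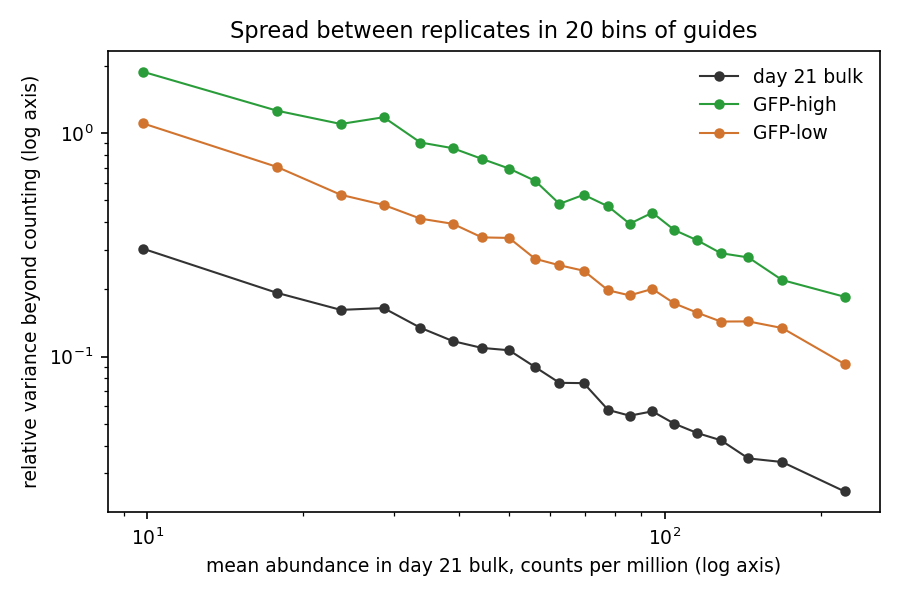
Relative variance between duplicates beyond counting (log axis) against mean abundance in day 21 unsorted cells (CPM, log axis), for guides in 20 bins of abundance, 1 point per bin and 1 line per group. In the lowest bin the variance was 0.304 at day 21, 1.11 in GFP-low and 1.88 in GFP-high cells, and in the highest bin it was 0.0249, 0.0926 and 0.185.

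Between day 0 and day 21, guides against genes of basic RNA and protein synthesis were lost from the unsorted culture. The lowest gene was RRM1, the large subunit of ribonucleotide reductase (chromosome 11, 4094707 to 4138876), which fell by 1.97 on the log2 scale (SE 0.31, 10 of 10 guides lower). Its level was 3.69 ± 0.08 log2 CPM at day 21 and 5.73 ± 0.03 at day 0 (SD, n = 2 libraries each). SF3B1, the branch-site recognition subunit of the spliceosome (chromosome 2, 197389784 to 197435091), fell by 1.76 (SE 0.25, 10 of 10 guides), and the spliceosomal genes CRNKL1 and PRPF8 fell by 1.62 and 1.42. CCT3, a chaperonin subunit, fell by 1.69, and MTPAP, the mitochondrial poly(A) polymerase, fell by 1.51. DDX55, a helicase of ribosome assembly, fell by 1.50, and MARS2 and VARS, which charge mitochondrial and cytosolic tRNA, fell by 1.43 and 1.38. DDX39B, an mRNA export helicase, fell by 1.42. Relative to the control guides, guide abundance was 7.09-fold lower for RRM1, 6.14-fold lower for SF3B1 and 4.72-fold lower for VARS.

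Control guides moved the other way on this scale, with a mean log2 fold change of 0.86, and their share of all counts went from 9.50% in each day 0 library to 16.1% in each day 21 library. AAVS1 guides averaged 0.75, Zhang guides 0.89 and CTRL guides 0.89, while the median gene was at −0.23. Genes called higher lay at the level of the control guides. They included NR0B1 (0.89), RBFOX1 (0.88), CPEB2 (0.84), ADAD2 (0.84), RBMXL3 (0.85) and REPIN1 (0.81). The others among the 10 with the smallest adjusted p were AUH (0.78), ZCCHC2 (0.76), ZNF579 (0.76) and ZCCHC3 (0.74). RBFOX1 is a splicing factor of neurons and muscle, and ADAD2 is known from the testis. With libraries scaled on control guides, all 10 of these values lay below 0, from −0.01 for NR0B1 to −0.16 for ZCCHC3. HNRNPA1 had a log2 fold change of 0.10 (SE 0.21) and KHDRBS1 −0.69 (SE 0.28), and neither passed. Relative to the control guides they were 1.69-fold and 2.92-fold lower, with adjusted p of 7.38e-05 and 2.16e-14 in limma's camera against control guides. That test called 1049 of 1144 genes lower, so it does not set either gene apart from the rest of the library.

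With edgeR and limma's camera, 112 of 1144 genes passed an adjusted p of 0.05 at day 21, 32 higher (EGFP among them) and 80 lower, and 374 had an unadjusted p under 0.05. The adjusted p was 0.00643 for RRM1, 0.0133 for the other 9 lower genes above, and from 0.0133 to 0.0202 for the 10 higher ones. With control-guide scaling SF3B1 and CRNKL1 lost their call (adjusted p = 0.0530 each in camera), at −2.65 and −2.51. PRPF8 and VARS lost theirs with fry (adjusted p = 0.0783 and 0.0562) and MARS2 with robust rank aggregation (adjusted p = 0.0507). The levels of the 2 days did not overlap between libraries for all 112 of these genes and for 89.7% of all genes. Chance would give 33.3% with libraries of equal spread. Day 0 duplicates lay much closer together than day 21 duplicates (SD of the log2 difference over guides 0.096 and 0.691), so chance gives more here. The split depended on the reference. Against control guides 1049 genes were lower and 0 higher by camera, and scaling on control guides, which shifted the median gene by −0.90, left 23 genes, 10 higher and 13 lower relative to that shift. With an estimated correlation camera called 0 genes, but its few degrees of freedom make calls over 1144 genes unlikely even for real changes. Robust rank aggregation called 68, fry 326 and counts summed per gene 383. Single guides gave 0 calls in edgeR, 2009 with an unadjusted p under 0.05, and 764 calls in DESeq2. The 0 in edgeR rests on a spread pooled over all groups, and far more single guides passed when only these 2 groups were fitted.

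Of the 19 lists, 10 passed at day 21, 9 lower and 1 higher than other guides. With an estimated correlation 9 of the 10 still passed, and cleavage and polyadenylation did not (adjusted p = 0.0907 with an estimated correlation). Guides against the 20 cytosolic aminoacyl-tRNA synthetases and their partners had the lowest mean, −0.99 (SD between genes 0.31). Of them 7 were called lower, 13 when adjusted over the list alone, among them QARS (−1.42) and LARS (−1.48). The core spliceosome (68 genes) averaged −0.74, with 12 called lower, 22 when adjusted over the list alone, among them SNRNP200 (−1.51). Ribosome biogenesis (46 genes) averaged −0.65, with 6 called lower, 9 adjusted over the list alone, among them DDX55 and UTP15 (−1.42). Cytosolic ribosomal proteins (77 genes) averaged −0.65, with 10 called lower, 12 adjusted over the list alone. They were led by RPL3 (−1.40), RPL11 (−1.60), RPL7 (−1.37) and RPL26 (−1.31). Guides against mRNA export and cap-binding genes (17) averaged −0.52, with 4 called lower. Adjusted over the list alone these were 5 lower and 1 higher, and THOC2 of the export complex THO fell by 1.56. Translation factors (46) averaged −0.47. Of them 7 were called lower and 1 higher, or 9 and 3 adjusted over the list alone, with EIF2B1 at −1.50 and EIF2S3 at −1.50. The EIF2S3 call was lost without day 21 replicate 1 (adjusted p = 0.0532 with camera).

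The 14 RNA exosome genes averaged −0.50 with 0 called singly, also 0 adjusted over the list alone. EXOSC8 was at −1.05 and DIS3 at −0.93. Mitochondrial RNA and ribosome genes (64) averaged −0.39, and 1, MTPAP, was called, also 1 adjusted over the list alone. Cleavage and polyadenylation genes (22) averaged −0.44 with 3 called lower, 3 adjusted over the list alone, led by NUDT21 (−1.25), a subunit that helps to choose poly(A) sites. Guides against 46 germline- and neuron-restricted RBPs averaged 0.35, with 5 called higher, 7 adjusted over the list alone, among them RBFOX1, RBMXL3 and NOVA2 (0.69). This average turned to −0.55 with control-guide scaling. Camera's adjusted p ran from 1.66e-10 for the synthetases and 2.16e-08 for the spliceosome to 0.0106 for cleavage and polyadenylation. It was 2.62e-06 for ribosome biogenesis, 1.2e-05 for ribosomal proteins, 2.27e-05 for the germline and neuron list, 0.00414 for the exosome and for mRNA export, 0.00586 for the mitochondrial list and 0.00603 for translation factors. With control-guide scaling the single calls of QARS, LARS, SNRNP200, UTP15, the 4 ribosomal genes named above, EIF2B1, EIF2S3 and NUDT21 were lost (adjusted p from 0.0519 to 0.0711 in camera), at log2 fold changes of −2.15 to −2.49. Calls were also lost for RPL11, RPL26 and SNRNP200 with fry, and for RPL26, EIF2S3, NUDT21 and NOVA2 with robust rank aggregation.

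**Figure D2:**
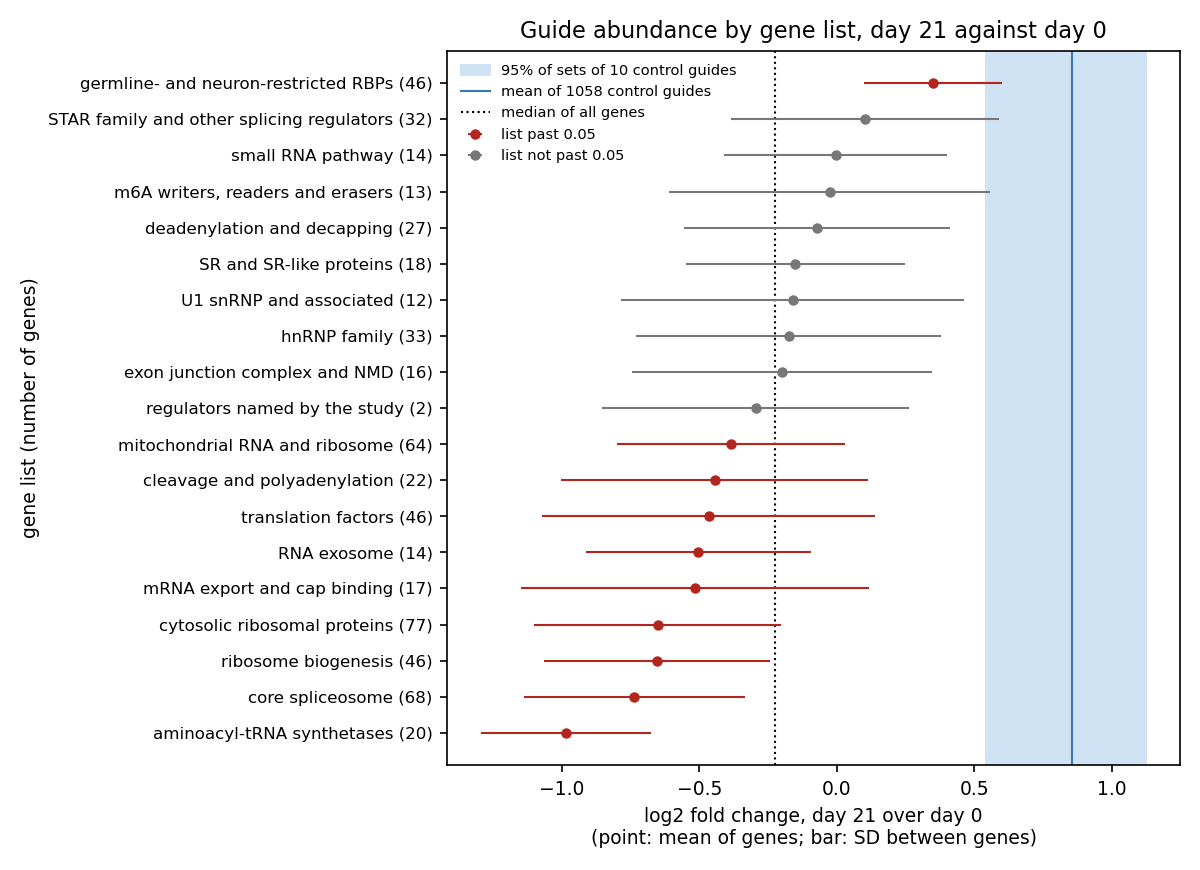
Mean log2 fold change of guide abundance, day 21 over day 0, for 19 gene lists (point, mean of genes; bar, SD between genes), with lists past an adjusted p of 0.05 in red, the mean of 1058 control guides as a blue line, 95% of sets of 10 control guides as a band (0.54 to 1.13) and the median gene as a dotted line. Means run from −0.99 for aminoacyl-tRNA synthetases to 0.35 for germline- and neuron-restricted RBPs, whose mean turns to −0.55 when libraries are scaled on control guides.

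The other 9 lists did not pass at day 21. STAR family and other splicing regulators (32 genes) averaged 0.10 (adjusted p = 0.137 in camera), with 3 called higher, also 3 adjusted over the list alone: KHDRBS3 (0.79), MBNL3 (0.68) and MSI2 (0.73). Of the 16 exon junction and nonsense-mediated decay genes (adjusted p = 0.606), 2 were called lower in both adjustments, EIF4A3 (−1.52) and UPF1 (−1.13). Of the 33 hnRNP genes (adjusted p = 0.852), 1 was called lower, HNRNPU (−1.21), and 0 adjusted over the list alone. Of the 12 genes of the U1 snRNP and its partners (adjusted p = 0.852), RBM25 was lower (−1.43) and TIA1 higher (0.68), both also adjusted over the list alone. Of the 13 m6A genes (adjusted p = 0.606), the readers YTHDC1 (−1.33) and YTHDF1 (0.62) were called, likewise in both adjustments. DCP1B (0.72) was called among 27 deadenylation and decapping genes (adjusted p = 0.744), with 0 adjusted over the list alone. SR proteins (18 genes, adjusted p = 0.715), the small RNA pathway (14 genes, adjusted p = 0.715) and the pair HNRNPA1 and KHDRBS1 (adjusted p = 0.573) had 0 calls in both adjustments. Mean, median and test differed in sign for 4 of these lists. The deadenylation and decapping list had a mean and median of −0.07 and −0.06 and a test toward higher values. The m6A list (mean −0.03, median 0.18) and the small RNA list (mean −0.00, median 0.15) had a test toward higher values, and the hnRNP list (mean −0.18, median 0.09) a test toward lower values.

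Among the cells sorted as GFP-low, guides named for EGFP were enriched over day 21 unsorted cells. Their mean log2 fold change was 2.57 (SE 0.85, 3 of 3 guides higher). EGFP_01 went from 195 ± 36.6 to 2298 ± 666 scaled CPM (SD, n = 2 libraries each), EGFP_02 from 160 ± 50.4 to 1559 ± 632, and EGFP_03 from 189 ± 74.3 to 349 ± 84.4. No RBP gene passed in this comparison. The nearest by p were CLK3, RBM7 and HNRNPA1, in that order. CLK3, a kinase of SR proteins, had a log2 fold change of −0.60 (9 of 10 guides lower), and RBM7, a subunit of a nuclear exosome targeting complex, of 0.53 (SE 0.16). HNRNPA1, an hnRNP that binds exonic and intronic splicing silencers (chromosome 12, 54280193 to 54287088), was at 0.60 (SE 0.22, 9 of 10 guides higher), with levels of 6.82 ± 0.36 in GFP-low and 6.24 ± 0.07 in unsorted cells. RBMX2 was at 0.54 and ADAT2 at 0.54, and on the lower side EIF4A1 was at −0.59, RPL10L at −0.58, RPA2 at −0.56 and PNLDC1 at −0.42. KHDRBS1 was at −0.09 (SE 0.17) and turned to 0.16 without day 21 replicate 1.

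For EGFP the adjusted p was 5.71e-10 in limma's camera on edgeR statistics. Of 1144 genes, 1 passed and 68 had an unadjusted p under 0.05. CLK3, RBM7 and HNRNPA1 each had an adjusted p of 0.178. Without GFP-low replicate 1 HNRNPA1 was at 0.31 (adjusted p = 0.969 in camera). It passed when only the 2 groups were fitted (adjusted p = 0.0388 in edgeR and camera) and in the voom fit chosen after seeing the data (adjusted p = 0.00983), and CLK3 passed without day 21 replicate 1 (adjusted p = 0.0429). None of the 19 lists passed in camera. The smallest adjusted p in limma's camera, 0.776, was that of the pair HNRNPA1 and KHDRBS1, which the study chose on these samples and which is no independent evidence. Adjusted over the list alone, HNRNPA1 passed in this pair and in the hnRNP list, and RBM7 in the exosome list, 1 gene each. With an estimated correlation the EGFP call was lost (adjusted p = 0.567, unadjusted p = 0.000496 with an estimated correlation), in a test with few degrees of freedom. The call was also lost with ranks, fry and robust rank aggregation (adjusted p = 0.739, 0.116 and 0.114). Ranks of 3 guides cannot reach the threshold over 1144 genes for a lone gene. With 20000 random draws, 0.114 is the smallest adjusted p that robust rank aggregation can give a lone gene. The losses with these 2 tests therefore do not argue against EGFP.

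In GFP-high cells no gene passed against day 21 unsorted cells. The highest was DDX41, an RNA helicase mutated in inherited myeloid neoplasms (chromosome 5, 177511577 to 177517469), with a log2 fold change of 1.19 (SE 0.23, 10 of 10 guides higher) and levels of 5.65 ± 0.26 against 4.59 ± 0.01. DDX41 was itself called lower at day 21 than at day 0 in unsorted cells (−1.31, adjusted p = 0.0133 in camera). Its value is thus taken against a depleted level. U2SURP, a U2 snRNP-associated protein, was at 1.01 (SE 0.45, 8 of 10 guides), GARS at 0.92, CARS2 at 0.64 and EIF2AK1 at 0.61. On the lower side PSMD7 was at −0.89 (SE 0.31), ANKRD17 at −0.89 and PCBP2 at −0.82. KHDRBS1, also called SAM68, an RNA-binding protein of the STAR family (chromosome 1, 32013829 to 32060850), was at 0.80 (SE 0.27, 9 of 10 guides higher). Its levels were 6.07 ± 0.88 and 5.43 ± 0.30. HNRNPA1 was at −0.01 (SE 0.23), and its sign turned with control-guide scaling (0.00) and with DESeq2 size factors (0.01).

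The adjusted p was 0.756 for DDX41 and 0.999 for the other genes named here, in limma's camera on edgeR statistics. The count of calls was 0, with 50 genes under an unadjusted p of 0.05. DESeq2, voom, summed counts, ranks and robust rank aggregation also called 0, and fry called 2, EXOSC1 and PRPF39. Robust rank aggregation could not have called a lone gene, because of the floor that its random draws set under its p-values. None of the 19 lists passed, the smallest adjusted p being 0.881, and adjusted over the list alone KHDRBS1 passed in the pair chosen by the study. Without GFP-high replicate 1 the value of KHDRBS1 was −0.02, that of GARS −0.11 and that of DDX41 0.78.

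Between GFP-high and GFP-low cells, EGFP guides were lower in GFP-high by the largest amount, with a mean log2 fold change of −2.65 (SE 1.31, 3 of 3 guides lower). EGFP_01 was at −4.05 and EGFP_02 at −3.86, and EGFP_03 at −0.03. Of the genes that did not pass, RPL7 was at −1.02, SNRPE, a core spliceosomal protein, at −0.94, and BOP1, a ribosome assembly factor, at −0.70. Higher in GFP-high, and also not passing, were RPA2 (0.96, 10 of 10 guides), RP9 (0.87, 10 of 10 guides), RPL10L (0.87), SART1 (0.78) and ENDOG (0.50). KHDRBS1 was at 0.89 (SE 0.32, 7 of 10 guides higher) and HNRNPA1 at −0.60 (SE 0.28, 7 of 10 guides lower). Without GFP-high replicate 1 KHDRBS1 was at 0.07, and without GFP-low replicate 1 HNRNPA1 was at −0.32.

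For EGFP the adjusted p was 0.0244 in limma's camera on edgeR statistics. It was the only call of 1144 genes, with 52 under an unadjusted p of 0.05. The call was lost without any of the 4 sorted libraries in turn (adjusted p = 0.820 and 0.989 without GFP-high replicates 1 and 2, and 0.198 and 0.335 without GFP-low replicates 1 and 2), while the log2 fold changes were −2.85, −2.57, −2.77 and −2.45 in that order. It was also lost with an estimated correlation (adjusted p = 0.999 with an estimated correlation), ranks, fry and robust rank aggregation. For a lone gene with so few guides, neither ranks nor robust rank aggregation could have reached the threshold. RP9 had an adjusted p of 0.407, and KHDRBS1 and HNRNPA1 of 0.922. With fry, which called 10 genes here, RP9 and RPL7 passed (adjusted p = 0.0385 and 0.00156 in fry). None of the 19 lists passed, the smallest adjusted p being 0.979. Adjusted over the list alone, KHDRBS1 passed as higher and HNRNPA1 as lower in the pair chosen by the study on these samples.

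**Figure D3:**
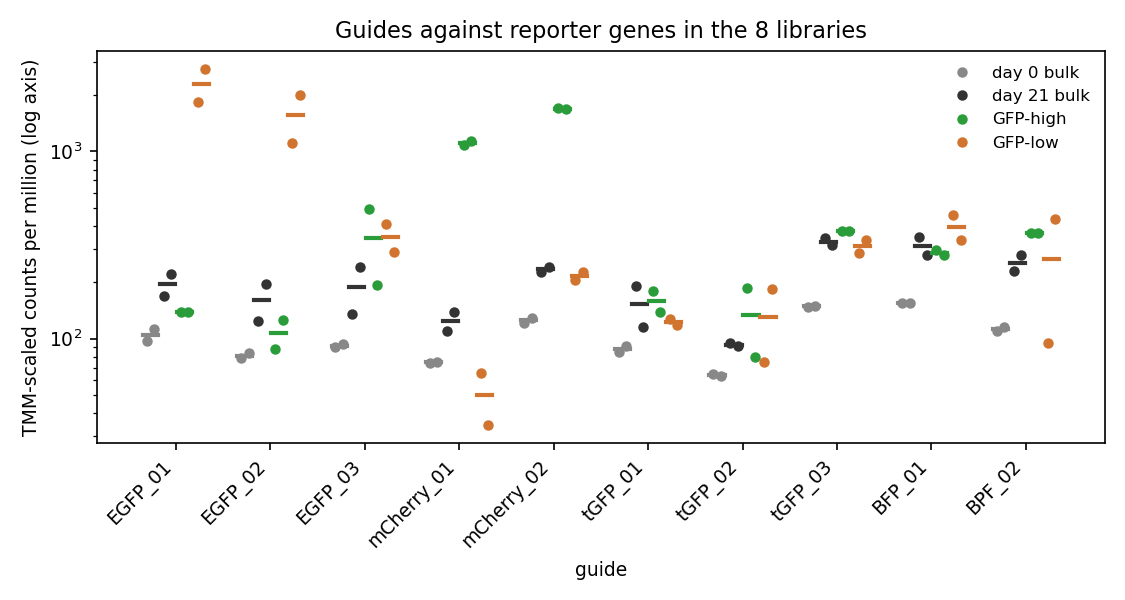
TMM-scaled CPM (log axis) of 10 guides named for fluorescent proteins, in 2 libraries of each of 4 groups (1 point per library, bar for the mean). EGFP_01 and EGFP_02 stand at 2298 and 1559 in GFP-low cells and mCherry_01 and mCherry_02 at 1102 and 1685 in GFP-high cells, while EGFP_03 is at 343 in GFP-high and 349 in GFP-low cells.

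**Figure D4:**
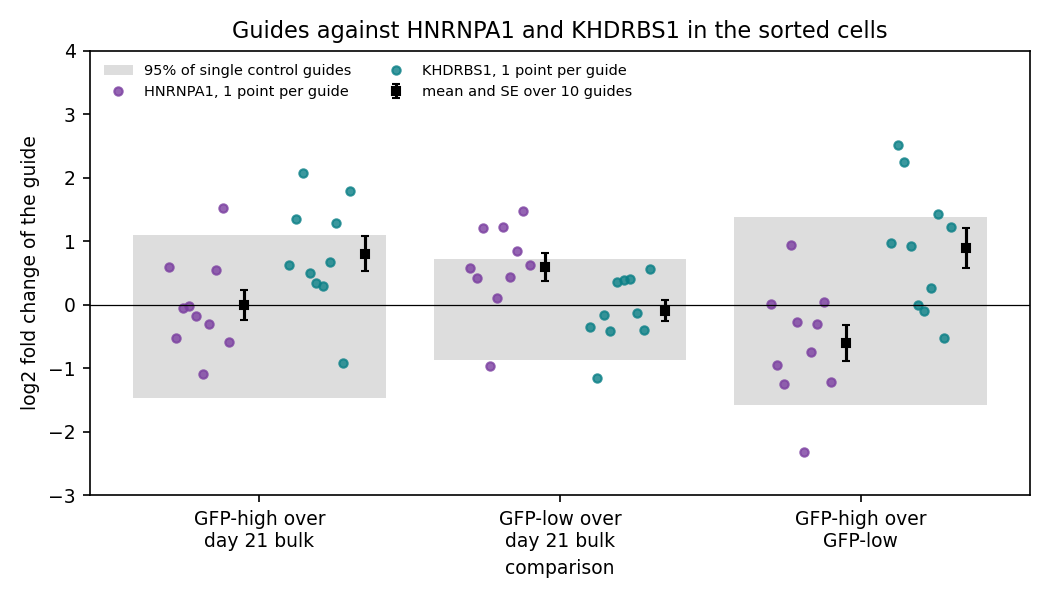
Log2 fold changes of the 10 guides against HNRNPA1 and the 10 against KHDRBS1 in 3 comparisons of sorted cells (1 point per guide; square, mean with SE over guides), with 95% of single control guides as a grey band. Control guides were on average more abundant than the guides of either gene, so the band is too narrow for them. Means are −0.01, 0.60 and −0.60 for HNRNPA1 and 0.80, −0.09 and 0.89 for KHDRBS1, and without GFP-high replicate 1 the first and last of the KHDRBS1 means are −0.02 and 0.07.

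Control guides give a background for the sorted comparisons, but one that is not matched on abundance. They averaged 7.09 log2 CPM in each day 21 unsorted library, against 6.24 for HNRNPA1, 5.43 for KHDRBS1 and 4.59 for DDX41. Spread between duplicates was larger for less abundant guides, so the ranges below are too narrow for such genes. Their mean log2 fold change was −0.02 in GFP-high and −0.01 in GFP-low cells against unsorted cells, and −0.01 between the sorted groups. Of sets of 10 control guides, 95% had a mean between −0.44 and 0.35 in GFP-high cells, between −0.26 and 0.22 in GFP-low cells and between −0.48 and 0.43 between the sorted groups. Single guides past the threshold in edgeR numbered 2, 1 and 4 in these comparisons, and 0 of 1058 control guides passed in any of them. All of those that passed were named for fluorescent proteins, and no guide against an RBP gene passed. They were mCherry_01 and mCherry_02 in GFP-high and EGFP_01 in GFP-low cells. Between the sorted groups they were EGFP_01, EGFP_02, mCherry_01 and mCherry_02. Of control guides, 9.64% had an unadjusted p under 0.05 in edgeR in GFP-high over unsorted cells, 1.98% in GFP-low and 14.1% between the sorted groups. Single-guide p-values thus ran too small in both comparisons with GFP-high cells and too large in GFP-low over unsorted cells. Of the 19 lists, none of which passed in camera, mean, median and test differed in sign for 4 in GFP-high, 4 in GFP-low and 6 between the sorted groups.

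Gene fold changes of GFP-high and of GFP-low cells over the shared day 21 libraries had a Pearson's r of 0.0701 and a covariance of 0.00461 across 1142 genes, which are not independent. In 100 simulations with no effect and with libraries drawn independently, the shared libraries gave a mean r of 0.185 (SD 0.0269) and a mean covariance of 0.0110 (SD 0.00172), and the observed minus simulated covariance was −0.00640. Replicate differences of the 3 day 21 groups correlated, though, at 0.152 to 0.310. Taken from these differences, with same-numbered libraries together, the covariance without an effect was 0.00503 (SD 0.00168 over 1000 bootstraps of genes), against an observed 0.00735 on the same scale. Averaged over the 4 ways to match library numbers it was 0.0129, above the observed value. The no-effect value thus depends on whether same-numbered libraries belong together. The use of replicate differences was chosen after seeing the data, and the gap to the simulation is not read as an effect. Each day 21 library alone would leave 1 library per side, so the controls were not split. Without day 21 replicate 1 r was 0.224 and without replicate 2 it was 0.234. A lone shared library puts more of its noise into both comparisons, which raises r without any effect.

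In the authors' deposited table, DDX41 (beta 0.871), U2SURP (0.861), NARS (0.765) and mCherry (2.11) had a false discovery rate at or under 0.05 in GFP-high cells. EGFP (2.04) and FTSJ3 (−0.413) did in GFP-low cells. The authors' deposited table gave KHDRBS1 a beta of 0.605 in GFP-high (false discovery rate 0.2) and HNRNPA1 a beta of 0.450 in GFP-low cells (false discovery rate 0.32). By its Wald test 0 genes passed. Over 1144 genes, Spearman's rho between the authors' deposited beta and the mean log2 fold change computed here was 0.932 for GFP-high and 0.931 for GFP-low cells against day 21 unsorted cells. NARS and FTSJ3 are named because the authors' table calls them, after their values were seen.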

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

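The counting, DNA-cutting, gene-specific growth, each-gene matched and single-library tests here were chosen only after the result was seen; the others were set before. Guides named for mCherry, which had too few guides per gene to enter the gene test, stood out between the sorted groups. The log2 fold change of GFP-high over GFP-low cells was 4.46 for mCherry_01 and 2.97 for mCherry_02, while the highest of 1058 control guides was at 2.52. In scaled CPM, mCherry_01 was at 1102 ± 38.9 in GFP-high and 49.9 ± 21.7 in GFP-low cells, and mCherry_02 at 1685 ± 13.0 and 215 ± 15.0 (SD, n = 2 libraries). What the reporter of the cells carries is not stated in the labels, and no explanation was tested.

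Duplicates of the sorted cells lay far apart, and counting of reads is argued against as the cause, since the chi-square per degree of freedom was 125.6 in GFP-high and 64.4 in GFP-low cells. Variance beyond counting fell with the abundance of a guide, with a log-log slope of −0.773 (95% bootstrap interval −0.807 to −0.734) in GFP-high and −0.777 (−0.826 to −0.730) in GFP-low cells. The slope was not particular to sorted cells, since it was −0.821 (−0.851 to −0.791) in day 21 unsorted cells, whose mean also set the bins. A candidate explanation is that few sorted cells carried each guide. It would need about 2.07 cells per guide in GFP-high and 3.90 in GFP-low cells at a bulk level of 62.6 CPM. Loss of template copies before PCR would give the same slope. In the lowest bin the need would be 0.531 and 0.903 cells per guide, so many guides there would have none. Of 12470 guides, 1 had a count of 0 in each GFP-high library, and 1 and 2 did in the GFP-low libraries. The figures assume that every cell or copy adds equally to the counts, which was not tested. Under that assumption the few counts of 0 argue against few cells or lost copies as the whole cause. Such sampling would also make the variance fall as 1 over abundance, and the observed slopes were shallower. The cause stays open. No biological explanation was tested, because the labels give none for a difference between duplicates.

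Guides against germline- and neuron-restricted RBPs, genes known mainly from germ cells or neurons, lay below control guides at day 21. A cost of cutting DNA that is alike at every locus would place AAVS1 guides, which also cut, at the level of the list. They lay 0.397 (log2) above the guides of the list (two-sided permutation p of 1e-05, the smallest that 100000 permutations can give). The permutation took single guides as units, although AAVS1 is 1 locus. So the gap argues only against a cost equal at every locus as the whole cause. A cost that differs between loci stays open. Growth effects that differ between the genes may take part. The SD between the 46 gene means was 0.251, against a mean of 0.181 when guides were shuffled among the genes (one-sided permutation p of 0.0004, highest shuffle 0.271). Off-target cutting and copy number were not tested and stay open, and Zhang guides lay 0.145 above AAVS1 guides (two-sided permutation p of 4e-05).

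KHDRBS1 guides were higher and HNRNPA1 guides lower in GFP-high than in GFP-low cells, at log2 fold changes of 0.89 and −0.60. Spread between guides without an effect of the gene remains a possible explanation of both, since sets of 10 gene guides matched on abundance reached as far in 0.679% of 100000 draws for KHDRBS1 and 2.08% for HNRNPA1, and these shares times the 1142 genes tested were 7.75 and 23.8, where a product under 0.05 would have argued against it. With sets matched to each gene's own guides, 8.08 (SD 2.82 if genes were independent) and 40.5 (SD 6.20) genes would lie as far out, and 10 and 54 did. Without GFP-high replicate 1 KHDRBS1 was at 0.0716, and without GFP-low replicate 1 HNRNPA1 was at −0.321, so with 2 libraries per group a single library cannot be told apart from an effect of either gene. A role of both genes in the sorted phenotype, which the study's design asks about, stays open and was not settled by these tests.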

How the results depend on the processing

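Tests with voom and group variances, with day 21 libraries only and with replicate differences were chosen only after the result was seen; all other alternatives here were set before. Of 900 values of called genes under alternatives, 754 kept both, 129 lost the call (45 of them with an estimated correlation, 21 with control-guide scaling, 17 with 1 library left out, 13 with robust rank aggregation, 10 with fry, 7 with control guides as the background, 6 with voom, 4 with ranks, 3 with summed counts, 2 with only the 2 groups and 1 with a replicate block) and 17 turned direction; of 893 values of genes not called, 838 kept both, 41 gained a call and 14 turned. Of 110 values of called lists 108 kept both, 1 lost the call (cleavage and polyadenylation, −0.444, with an estimated correlation) and 1 turned (germline and neuron list, −0.549, with control-guide scaling). For single genes the estimated correlation has few degrees of freedom, so its 45 lost calls say little about these genes.

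Replicate numbers were not treated as pairs, since nothing in the labels ties them. The replicate differences did correlate, at 0.0954 for day 0 and GFP-low and at 0.142 to 0.310 for the other pairs of groups. Those of day 21 unsorted cells correlated at 0.247 with GFP-high and 0.310 with GFP-low. Same-numbered libraries may thus share deviations, which the main fit ignores. With a replicate block 112 genes passed at day 21, 34 higher and 78 lower, of which 102 were among the 112 without it. It called 2 guides in GFP-low over unsorted cells and put the control guides at 0.8375 at day 21, and it moved no other count of calls by over 1.5 times.

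Single guides past the threshold in GFP-high over unsorted cells numbered 2, and 1 with library totals, 0 with only the 2 groups, 4 with voom, 257 with DESeq2 and 0 to 1453 with 1 library left out (1453 without GFP-high replicate 2). In GFP-low they numbered 1, and 2 with day 21 libraries only, 2 with voom, 4 with DESeq2 and 0 to 0 with 1 library left out. Between the sorted groups they numbered 4, and 787 with DESeq2 and 3 to 2106 with 1 library left out (2106 without GFP-high replicate 2, 131 without replicate 1). At day 21 they numbered 0, and 5449 with only the 2 groups, 6226 with voom and 764 with DESeq2. The main fit pooled 1 spread over groups whose biological coefficient of variation ran from 2.68% at day 0 to 73.2% in GFP-high cells. Many guides passed at day 21 without the sorted libraries or with a variance per group. So the 0 does not mean that no guide changed. With 1 library left out, the lone library is assumed to vary like the other groups. The cause of the other differences was not tested.

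Genes past the threshold numbered 2 with fry in GFP-high. In GFP-low they numbered 2 with only the 2 groups, 2 with voom, 3 with fry, 0 with an estimated correlation, 0 with ranks, 0 with robust rank aggregation, 0 with 5 or more guides per gene, which removes EGFP, and 1 to 2 with 1 library left out. Between the sorted groups they numbered 10 with fry, 2 with DESeq2, 0 with an estimated correlation, 0 with ranks, 0 with robust rank aggregation, 0 with 5 or more guides and 0 to 0 with 1 library left out. At day 21 they numbered 23 with control-guide scaling, 0 with an estimated correlation, 326 with fry, 1049 with control guides as the background, 68 with robust rank aggregation and 383 with summed counts. With 1 library left out, 77 to 117 genes passed, and 73 of the 77 without day 21 replicate 1 were among the 112. Lists past the threshold with fry, which does not compare a list with other guides, numbered 2 in GFP-high and 2 between the sorted groups. The estimated correlation has few degrees of freedom. Ranks and robust rank aggregation cannot call a lone gene with few guides, such as EGFP. Beyond these limits, 5 or more guides and fry's other question, the cause was not tested.

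Genes that turned under control-guide scaling at day 21, by the shift of all guides that this scaling makes, were NR0B1 (−0.00726), RBFOX1 (−0.0153), CPEB2 (−0.0605), REPIN1 (−0.0924), ZCCHC2 (−0.134), ZNF579 (−0.143), ADAD2 (−0.0618), RBMXL3 (−0.0491), AUH (−0.119), ZCCHC3 (−0.157), HNRNPA1 (−0.799), FASTK (−0.202), NOVA2 (−0.213) and CELF4 (−0.176). With control guides as the background the test turned to lower while the value stayed, by the higher level of the background, for RBMXL3 (0.850), AUH (0.781), ZCCHC3 (0.742), HNRNPA1 (0.0999), FASTK (0.697), NOVA2 (0.686) and CELF4 (0.723). HNRNPA1 at day 21 was −0.0619 with library totals. In GFP-high HNRNPA1 was 0.00893 with DESeq2 size factors, 0.00424 with control-guide scaling, 0.00899 with DESeq2 and −0.361 to 0.0619 with 1 library left out. KHDRBS1 was −0.0187 to 1.23 in GFP-high and −0.364 to 0.162 in GFP-low with 1 library left out, where robust rank aggregation ranked it higher at a mean of −0.0901. GARS was −0.108 to 1.29 in GFP-high with 1 library left out, and for these 3 genes the cause was not tested.

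The correlation of the sorted groups' fold changes was 0.0258 with medians over guides and 0.224 to 0.234 with 1 day 21 library left out, where the noise of the lone shared library raises it. Its covariance without an effect was 0.00503 from replicate differences with same-numbered libraries together and 0.0129 over the 4 ways to match numbers. It was 0.0110 in the simulation, which drew libraries independently. Agreement with the authors' deposited table was 0.816 and 0.850 with medians. Control guides were at −0.214, −0.0765, −0.138 and 0.693 with library totals in the order GFP-high, GFP-low, between them and day 21, and at day 21 at 0.875 with DESeq2 size factors and −0.0442 with control-guide scaling. With 1 library left out they were at −0.194 to −0.00486, −0.101 to 0.00747, −0.183 to 0.0778 and 0.837 to 0.856. Except for the correlation with 1 day 21 library left out, the cause was not tested. Counting gave an error of 3.43% to 6.26% at the median guide, and guides at the 10th percentile had 29 counts in each GFP-high library and 40 and 62 in GFP-low.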

Other observations

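The groups of this part were formed only after their genes' values were seen, and the test of growth against GFP was set before. Of the 112 genes called at day 21, 44 human genes, 25 lower and 19 higher, lay outside the 19 lists, and 11 of the lower ones belonged to the 4 groups below. All 17 mitochondrial aminoacyl-tRNA synthetases in the library were taken by symbol. Their guides had a mean log2 fold change of −0.76 (SD between genes 0.41), with 5 called lower, among them MARS2 (−1.43), YARS2 (−1.22), RARS2 (−1.08) and TARS2 (−0.99). The 10 proteasome subunits averaged −0.84, with PSMD1 (−1.45), PSMB3 (−1.16) and PSMA3 (−1.15) called. The 4 subunits of the chaperonin CCT averaged −0.98, with CCT3 called, and the 3 subunits of the COPI vesicle coat averaged −1.09, with COPB1 (−1.50) and ARCN1 (−1.18) called. Adjusted over these 4 groups, limma's camera gave p of 5.93e-07, 1.14e-05, 2.1e-05 and 2.1e-05, and with an estimated correlation 0.0119, 0.0245, 0.0148 and 0.0770, which loses the COPI group. Because members were noticed as called, these p-values are no independent evidence. With an estimated correlation 0 single genes passed, in a test that its few degrees of freedom make hard for single genes to pass.

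A hypothesis was that loss of a gene from the culture goes with a shift in GFP. Across 1142 genes, which are not independent, Spearman's rho between the day 21 over day 0 and the GFP-high over GFP-low log2 fold changes was −0.0425 (two-sided permutation p of 0.15, 100000 permutations). Its SD over permutations was 0.0296, so the data neither showed such a relation nor excluded a weak one.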
